A study of Mus musculus with 8 samples.

How the data were processed

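RNA of sorted luminal cells from mouse prostate tumours was extracted with RNeasy micro columns and made into libraries with Ovation Solo kits, per the labels' protocols. The reads were handled with FastQC, Trimmomatic, STAR 2.7.5a, Picard and HTSeq 0.11.1 on GRCm38 (mm10), per the submitters' processing notes. The gene annotation, the strand setting of the counting and filters are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited values are a score: whole numbers per gene that sum to 20009480 to 20015305 in each of the 8 libraries, as gene counts scaled to 1 common total and rounded up would give. That reading rests on the values, since no header states it. Dividing by 20 gave CPM.

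The scaled values fall on steps. For each library a single step size was found at which 99.78% to 99.92% of the values above 0 equal a whole number of reads times the step, rounded up, against 14.5% to 39.4% of values by chance. This gave 7874802, 7210127 and 7280420 reads in basal-derived AD, 7286199 and 7296999 in basal-derived VP, and 7498369, 7873057 and 2904847 in luminal-derived AD replicates 1, 2 and 3. A count of 0 with a floor of 3 reads allows up to 0.381 to 0.416 CPM in the deeper libraries and 1.03 CPM in luminal-derived AD replicate 3. As deposited, with the rounding not undone, 42.1% to 61.4% of the values up to 20 times the smallest lay within 0.1 of a whole multiple of 1 step in the 7 deeper libraries and 98.3% in luminal-derived AD replicate 3. The reads, and the floors, counting intervals and limma-voom fit that use them, are therefore estimates that rest on the rounding being upward. In libraries simulated with that same scaling and rounding the method returned 100% of reads, which does not test that reading of the deposited values. Mitochondrially encoded genes took 2.71% to 3.84% of reads. Ribosomal RNA related features took 4.45% to 6.03%, and 12.5% in luminal-derived AD replicate 3. Counting intervals are exact binomial at 95% and, like floors, cover counting error only.

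Groups were taken from the sample titles. The fixed design named a count test for deposited counts and limma-trend on log2 values otherwise. Since the values were scaled, limma 3.58.1 in R 4.3.3 was run with trend and robust moderation on log2(value + 1), a pseudocount of 0.05 CPM, in 1 fit of all 8 libraries in 3 groups. Fold changes are on that scale and understate changes of low genes. Genes needed a deposited value of 20 (1 CPM) in at least 2 libraries, and Benjamini-Hochberg adjusted p under 0.05 was the threshold, two-sided. Fits on simulated data with 200 changed genes recovered 55% of changed genes at 2-fold and 90% at 4-fold in the first comparison (3.27% of calls false, 18824 genes), and 50% and 92% in the second (3.92% false, 18810 genes). With no gene changed there were 0 calls in either comparison. Changes were planted only in genes with means well above the filter, and the largest gene-wise spreads were capped. Noise was independent between genes, so these rates do not carry over to low or highly variable genes. The 200 leave out a further set, planted at 1.5-fold for the list test, whose calls were not counted as false. Coordinates came from GENCODE M21 on GRCm38, matched by Ensembl identifier for 18780 of the 18845 tested genes.

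The text names, by a rule fixed before the data were examined, the 12 genes with the largest rise and the 12 with the largest fall per comparison among genes past the threshold. These needed a mean of at least 1 log2 CPM and groups that do not overlap. Predicted or unnamed genes were passed over, including clone names starting with RP23 or RP24, a pattern added when the table was read. The rule adds lineage genes and Pten, and up to 4 members of each list. For the third comparison only genes named elsewhere are named. Lamc2, Sprr1a, Col6a3 and Krt80, single members that moved against the others of their lists, and Sbp were named after their values were seen. All genes past the threshold had groups that do not overlap, as did 29.8%, 44.0% and 37.5% of all genes in the 3 comparisons, against 10% by chance for 3 against 3 and 20% for 2 against 3.

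Lists of pathway genes and markers were fixed before the data were examined: basal, luminal and proximal luminal epithelium, secretory proteins, Hox patterning, androgen response, NF-kB targets, innate effectors, interferon response, MHC class I and II, cell cycle, mesenchymal genes, squamous differentiation, neuroendocrine genes, PI3K and FOXO feedback, p53 and senescence, hypoxia and glycolysis, cholesterol synthesis, unfolded protein response, immediate-early genes, myeloid cells, neutrophils, lymphocytes, fibroblasts, smooth muscle, endothelium, seminal vesicle, glia, red blood cells and mitochondrially encoded genes. Of 31 lists 30 had at least 5 tested members, and the red blood cell list had 1, Alas2, at 6.52 CPM in basal-derived AD, 4.42 CPM in basal-derived VP and 5.28 CPM in luminal-derived AD libraries. They were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, and again with an estimated correlation and with fry. Camera called 16, 17 and 18 lists in the 3 comparisons, fry called 10, 14 and 14, and camera with an estimated correlation called 0 in each (1, 4 and 4 lists at an unadjusted p under 0.05).

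Alternatives were median-of-ratios, upper-quartile and trimmed-mean scaling, other filters and pseudocounts, limma-voom with sample weights on recovered reads, a test against a 1.5-fold change, only the groups compared, a replicate block, the mean of both basal-derived groups, sets of genes left out, and each library left out in turn. The limma-voom fit also used the median-of-ratios factors, so it is not a separate check of the scaling. Chi-square values per gene over pairs of the same group were 3.84 to 25.3, which was used only to look for a library deposited more than once, and none of the 7 pairs agreed as closely as that would give. No deposited column was left unused.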

Results

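Luminal cells were sorted by flow cytometry from prostate tumours of 2 mouse models that carry the name of Pten, a phosphatase that opposes PI3K signalling, and their RNA was sequenced. Cells of the model named K5-PTEN are called basal-derived here and cells of the model named K8-PTEN luminal-derived, after the sample titles and the design text of the series. Basal-derived cells came from the anterior and dorsal lobes (AD, 3 libraries) or the ventral lobe (VP, 2 libraries), and luminal-derived cells from the anterior and dorsal lobes (3 libraries). The deposited table held 49671 genes, of which 18845 reached 1 CPM (the deposited value divided by 20) in at least 2 libraries and were tested. The values corresponded to 7210127 to 7874802 gene-assigned reads in 7 libraries and to 2904847 in luminal-derived AD replicate 3. One read was worth 0.127 to 0.139 CPM in those 7 libraries and 0.344 CPM in the shallow one. Pearson correlations of log2 values were 0.927 to 0.978 over the 7 pairs of libraries of the same group and 0.866 to 0.945 over the 21 pairs from different groups. No label states that the libraries of a group came from separate animals, so the p-values measure the spread between these samples.

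The first comparison asked how luminal tumour cells of basal origin differed from those of luminal origin within the anterior and dorsal lobes. Both kinds of cell had high levels of the luminal keratins: Krt8 stood at 1947 ± 223 CPM in basal-derived and 2102 ± 157 CPM in luminal-derived libraries (SD, n = 3 each). The basal keratins were higher in the basal-derived cells. Krt5 was 8.43-fold higher (92.6 ± 4.46 against 11.03 ± 1.85 CPM, limma adjusted p = 2.19e-06) and Krt14 was 4.86-fold higher (112 ± 16.0 against 23 ± 2.10 CPM, limma adjusted p = 7.46e-06). Krt15, which marks basal and progenitor cells of stratified epithelia, was 17.5-fold higher, at 730 ± 43.7 against 42.4 ± 10.5 CPM (log2 fold change 4.13, SE 0.33, limma adjusted p = 0.000373). It lies on chromosome 11 at 100131758 to 100135928 (GRCm38). Trp63, the transcription factor of basal epithelium, was 3.64-fold higher (limma adjusted p = 0.012), and without basal-derived AD replicate 1 its adjusted p was 0.0676. The androgen receptor gene Ar was 1.81-fold higher (311 ± 18.3 against 173 ± 19.3 CPM, limma adjusted p = 0.00258), while Nkx3-1, an androgen-regulated homeobox gene of prostate epithelium, was 17.2-fold lower (0.80 ± 0.20 against 14.5 ± 3.26 CPM, limma adjusted p = 0.000517). Pten itself differed by 0.27 on the log2 scale (limma adjusted p = 0.254). Both arms carry the Pten model, and reads outside a deleted part of a gene do not test its loss. Krt18 and Epcam did not pass the threshold, with adjusted p of 0.342 and 0.303 by limma.

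**Figure D1:**
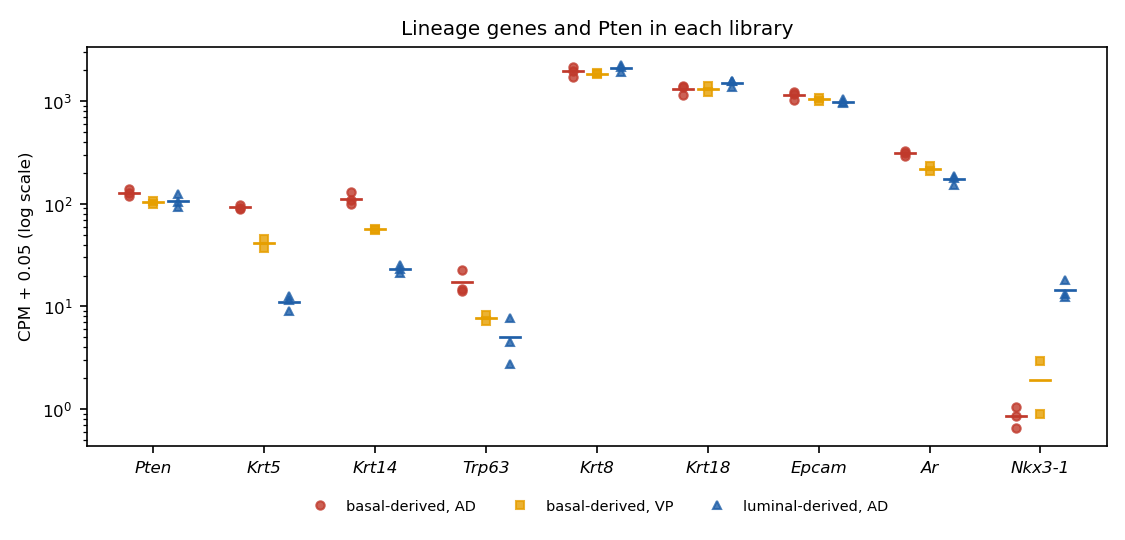
Levels of Pten, basal and luminal lineage genes and androgen-related genes in each library, as CPM plus 0.05 on a log axis. Each symbol is 1 library and each short line a group mean, and Krt5 stands at a mean of 92.6 CPM in basal-derived AD, 41.6 CPM in basal-derived VP and 11.03 CPM in luminal-derived AD libraries.

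Among the 12 lower genes picked by size, those that fell most in basal-derived AD cells were Pbsn and Tgm4, which encode secreted prostate proteins. Probasin (Pbsn, chromosome X, 77837901 to 77853623) was 90.7-fold lower, at 1.92 ± 0.29 against 186 ± 63.0 CPM (log2 fold change -6.50, SE 0.28, limma adjusted p = 5.41e-07). Tgm4, the prostate transglutaminase, was 59.8-fold lower (8.67 ± 1.94 against 529 ± 158 CPM). The mucin genes Muc5b and Muc2 were 36.8-fold and 30.5-fold lower. Ptprz1, C1s2, Xkr4 and Mmp16 were 11.04-fold, 16.1-fold, 6.71-fold and 6.05-fold lower, and Mmp16 had limma adjusted p of 0.0603 and 0.0651 without basal-derived AD replicate 1 or 3. Lyz1, Peg10 and Defb50 completed the 12 lower genes with limma adjusted p of 0.039, 0.0433 and 0.0485. Leaving out any 1 of the basal-derived AD libraries ended all 3 calls, as did luminal-derived AD replicate 1 or 2 for Lyz1, every library except luminal-derived AD replicate 1 for Peg10, and every library except luminal-derived AD replicate 2 for Defb50 (limma adjusted p of 0.0515 to 0.148). Among the higher genes, Hdac9, a histone deacetylase, stood at 44.9 ± 7.32 against 3.05 ± 0.95 CPM (14.8-fold, limma adjusted p = 8.62e-06). The epithelial protease inhibitor gene Spink5 was 22.3-fold higher (643 ± 249 against 29.8 ± 15.1 CPM, limma adjusted p = 0.0234), and its limma adjusted p was 0.0574 to 0.0772 without basal-derived AD replicate 2 or 3 or luminal-derived AD replicate 2 or 3. Aqp4, a water channel, had 343 reads over the basal-derived and 3 over the luminal-derived AD libraries, a ratio of 93.4 with a 95% counting interval of 31.7 to 455. The desmosomal cadherin Dsc3 was 19.5-fold higher, the transcription factor Grhl3 was 13.9-fold higher and the acute-phase gene Saa1 was 14.3-fold higher. BC100530 and Dapl1 were 34.2-fold and 15.2-fold higher. Bbox1, Gdpd2 and Tmprss11b averaged under 8 CPM in both groups, with limma adjusted p of 0.0299, 0.0223 and 0.0213. Leaving out any 1 basal-derived AD library ended these 3 calls, and luminal-derived AD replicate 2 did so for Bbox1 and Gdpd2 (limma adjusted p of 0.0608 to 0.106). Reads of Saa1, Lyz1 and BC100530 can be shared with close relatives in the genome.

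**Figure D2:**
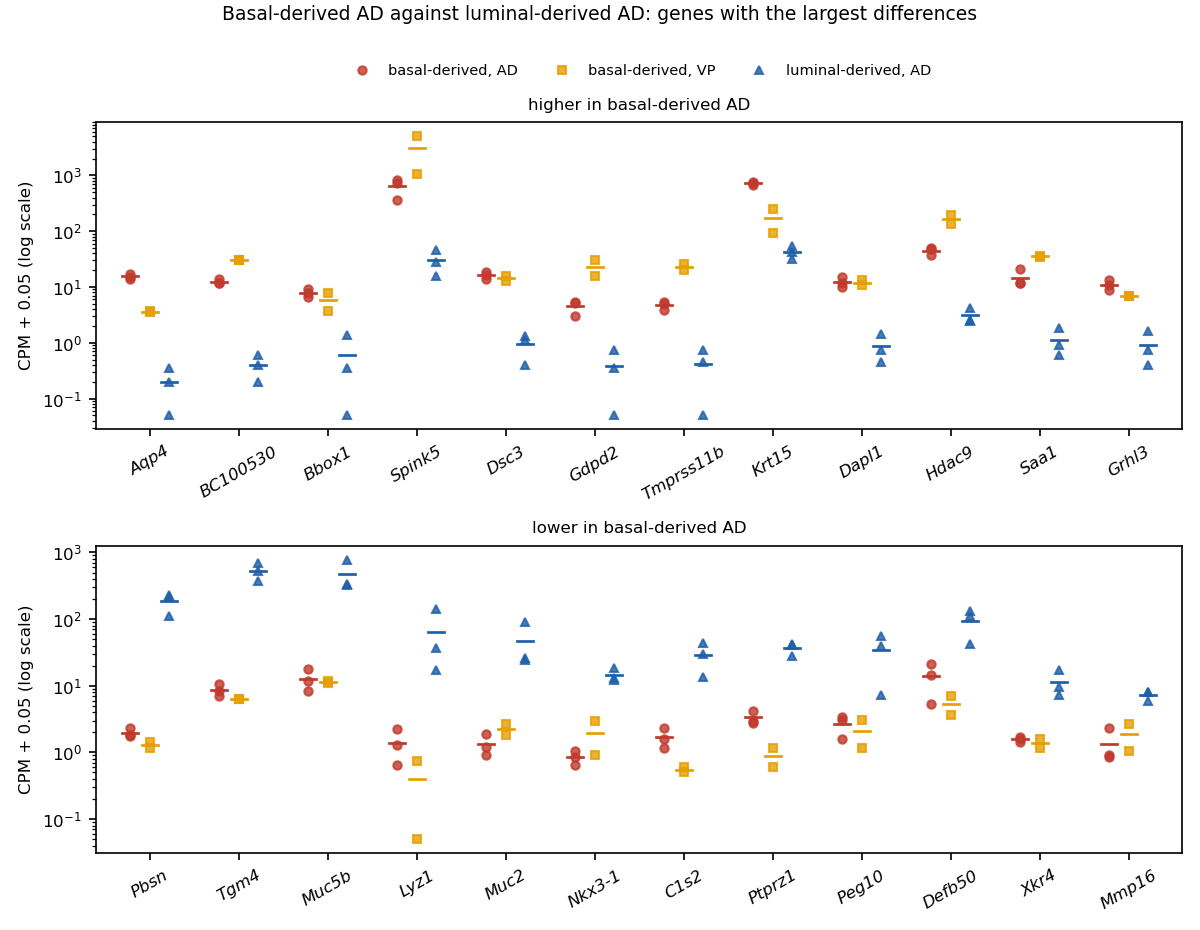
The 12 higher and the 12 lower genes that the naming rule picked in basal-derived against luminal-derived AD cells, per library. The rule passes over genes with a mean under 1 log2 CPM, whatever their change. Values are CPM plus 0.05 on a log axis, with short lines at group means. The ventral libraries are drawn for reference, and Pbsn lies at 1.92 CPM on average in basal-derived AD and at 186 CPM in luminal-derived AD libraries.

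Gene lists fixed before the data were examined describe these changes by theme. Of 20 basal epithelial genes 6 rose and 1, Lamc2, fell (camera adjusted p = 3.03e-05, and adjusted p = 0.614 with an estimated correlation). Adjusted over the list alone, 9 rose and 2 fell. Lamc2 lost its call without any 1 of the basal-derived AD libraries or luminal-derived AD replicate 1 or 2 (limma adjusted p of 0.0725 to 0.139). Of 22 genes of squamous differentiation 7 rose and 1, Sprr1a, fell, with Krt16 7.89-fold, Pkp1 5.75-fold and Krt6a 2.22-fold higher (camera adjusted p = 2.33e-05, adjusted p = 0.293 with an estimated correlation). That count was 11 higher and 1 lower adjusted over the list alone. Without any 1 basal-derived AD library 4 rose, and Sprr1a lost its call without these or luminal-derived AD replicate 2 or 3 (limma adjusted p of 0.0609 to 0.119). Of 20 Hox and regional patterning genes 8 rose and 2 fell, and 11 rose and 2 fell adjusted over the list alone. Over all genes 4 rose and 1 fell without any 1 basal-derived AD library, and 5 rose and 1 fell without luminal-derived AD replicate 2 or 3. Hoxa13 and Hoxd13 were 6.04-fold and 5.76-fold higher. The list had a camera adjusted p of 0.00888, an adjusted p = 0.614 with an estimated correlation, and 0.0758 by camera without luminal-derived AD replicate 1. Of 17 secretory protein genes 6 fell and 1, Spink5, rose, and 6 fell and 5 rose adjusted over the list alone. Msmb, a secreted prostate protein, fell 84.7-fold. The median log2 change of this list was -0.27 and its mean 0.24, against a test in the lower direction (camera adjusted p = 0.0282, adjusted p = 0.614 with an estimated correlation). Without luminal-derived AD replicate 3 there were 4 higher and 4 lower, 3 lower without basal-derived AD replicate 1, and none higher without basal-derived AD replicate 2 or 3. Its camera adjusted p was 0.571 without luminal-derived AD replicate 3 and 0.0685 without basal-derived AD replicate 1, and 0.0736 to 0.284 with trimmed-mean, median-of-ratios or upper-quartile scaling or limma-voom.

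Camera called the innate effector and interferon response lists higher and the NF-kB targets lower in basal-derived AD cells, and none of the 3 passed with an estimated correlation (adjusted p of 0.614, 0.614 and 0.662). Of 34 innate effectors 8 rose and none fell, 14 rose adjusted over the list alone (3 to 5 over all genes without any 1 basal-derived AD library or luminal-derived AD replicate 1 or 3), and the examples were Saa3 (7.35-fold), Chil1 (6.46-fold) and the receptor gene Tlr1 (3.28-fold, limma adjusted p of 0.0535 without basal-derived AD replicate 1). The camera adjusted p was 0.000261, with an adjusted p = 0.614 with an estimated correlation. Neutrophil markers moved with this list: Csf3r was 5.996-fold and Il1r2 4.29-fold higher, 2 of 7 markers rose (4 adjusted over the list alone), and the camera adjusted p was 0.000752 (adjusted p = 0.614 with an estimated correlation). Without basal-derived AD replicate 1 or 2 only 1 of the 7 rose, and Il1r2 had limma adjusted p of 0.0785 and 0.0794. Of 36 interferon response genes 4 rose, and 19 rose adjusted over the list alone. The count of 4 was 0 without any 1 basal-derived AD library, 1, 2 and 20 without luminal-derived AD replicate 2, 3 or 1, and 14 and 12 without ventral replicate 1 or 2, while the list was called by camera each time. Ifit1 was 2.30-fold and Xaf1 2.46-fold higher (camera adjusted p = 1e-07, adjusted p = 0.614 with an estimated correlation). Both lost their calls without any 1 basal-derived AD library or luminal-derived AD replicate 2, Xaf1 also without luminal-derived AD replicate 3 and Ifit1 with no filter on low values (limma adjusted p of 0.0588 to 0.1). Of 32 NF-kB targets 3 fell, and 4 fell adjusted over the list alone. Over all genes none fell without any 1 basal-derived AD library, 1 fell without luminal-derived AD replicate 1, and 4 rose and none fell without luminal-derived AD replicate 2. Without either ventral library 1 rose and 4 fell. Icam1 was 1.98-fold lower, at 162 ± 16.7 against 331 ± 109 CPM, and the subunit genes Relb and Nfkb2 were 1.43-fold and 1.41-fold lower. All 3 genes lost their calls without any 1 basal-derived AD library or luminal-derived AD replicate 2 (limma adjusted p of 0.0734 to 0.16), Icam1 and Relb also without luminal-derived AD replicate 1 (0.0594 and 0.0524), Nfkb2 without luminal-derived AD replicate 3 (0.0717) and Icam1 with no filter on low values (0.0762). The list had a camera adjusted p of 0.00225 and an adjusted p = 0.662 with an estimated correlation. Luminal-derived AD replicate 2 decided that call, which had a median of 0.03 and a camera adjusted p of 0.812 without it.

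Of 35 cell cycle genes 7 rose in basal-derived AD cells over all genes and 17 adjusted over the list alone, among them Top2a (2.64-fold), Mki67 (2.36-fold) and Mcm6 (1.85-fold). The camera adjusted p was 9.94e-07 (adjusted p = 0.614 with an estimated correlation). The count of 7 was 1, 2 and 2 without basal-derived AD replicate 1, 2 or 3, 12, 2 and 4 without luminal-derived AD replicate 1, 2 or 3, and 10 without ventral replicate 1. Mki67 lost its call without any 1 basal-derived AD library or luminal-derived AD replicate 2, and Top2a without basal-derived AD replicate 1 (limma adjusted p of 0.0507 to 0.0813). Of 26 immediate-early and dissociation genes 5 rose, and 11 rose and 1 fell adjusted over the list alone, with Fos at 2046 ± 201 against 1185 ± 159 CPM. The camera adjusted p was 0.011 (adjusted p = 0.662 with an estimated correlation), and 0.332 without luminal-derived AD replicate 1. The count of 5 was 1 without basal-derived AD replicate 1 or 3, where Fos had limma adjusted p of 0.0559 and 0.0575, 3 without luminal-derived AD replicate 2 and 10 without either ventral library. Of 23 mesenchymal genes 4 rose (11 rose and 2 fell adjusted over the list alone), among them Tgfb1 (1.77-fold), Mmp2 (2.57-fold) and Sparc (2.22-fold) (camera adjusted p = 0.00888, adjusted p = 0.614 with an estimated correlation). That count of 4 was 1 and 0 without basal-derived AD replicate 1 or 2 and 7 without ventral replicate 1, while 1 fell without luminal-derived AD replicate 1 or 3 and 2 fell without either ventral library. Tgfb1 and Mmp2 lost their calls without basal-derived AD replicate 1 or 2, and Sparc without basal-derived AD replicate 2 or luminal-derived AD replicate 3 (limma adjusted p of 0.0507 to 0.0832). Fibroblast markers moved with them, 6 of 18 higher and Gsn lower (10 higher and 2 lower adjusted over the list alone), and summed to 972 against 711 CPM (camera adjusted p = 0.00107, adjusted p = 0.614 with an estimated correlation). Of the fibroblast markers 3 rose without basal-derived AD replicate 1 or 3, and 2 fell without luminal-derived AD replicate 2. Of 26 hypoxia and glycolysis genes 3 rose and 1 fell (12 and 1 adjusted over the list alone), led by Car12, a carbonic anhydrase gene, 6.94-fold higher (camera adjusted p = 0.0148, adjusted p = 0.614 with an estimated correlation). That camera adjusted p was 0.104 with upper-quartile scaling, 0.0506 with median-of-ratios scaling and 0.0503 without basal-derived AD replicate 3. Of these genes 1 rose without any 1 basal-derived AD library, 5 rose without luminal-derived AD replicate 1 or either ventral library, and none fell without basal-derived AD replicate 1 or 3. Of 25 cholesterol synthesis genes 3 rose (4 adjusted over the list alone), Sc5d, Nsdhl and Cyp51 (camera adjusted p = 0.0162, adjusted p = 0.709 with an estimated correlation). That call ended without basal-derived AD replicate 3 (adjusted p = 0.135) or luminal-derived AD replicate 2 (adjusted p = 0.812). None of the 3 rose without basal-derived AD replicate 1 or 3, and Sc5d alone without basal-derived AD replicate 2 or luminal-derived AD replicate 2 or 3 (limma adjusted p of the lost calls 0.0524 to 0.133). Of 24 unfolded protein response genes 1 rose (Atf3) and 1 fell (Chac1), with 1 rising and 3 falling adjusted over the list alone. The camera adjusted p in the lower direction was 0.000466 (adjusted p = 0.614 with an estimated correlation), and 0.114 without luminal-derived AD replicate 2. Atf3 lost its call without any 1 basal-derived AD library or luminal-derived AD replicate 2 or 3 and with upper-quartile scaling (limma adjusted p of 0.0552 to 0.119). The count of 1 that fell was 2 without luminal-derived AD replicate 1 and 4 and 3 without ventral replicate 1 or 2.

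Seminal vesicle transcripts separated the libraries in another way. The 10 genes summed to 3516, 2149 and 1555 CPM in the basal-derived AD libraries, to 25.95, 2.30 and 2700 CPM in luminal-derived AD replicates 1, 2 and 3, and to 2.75 and 0.60 CPM in the ventral libraries. None of the 10 passed the gene-wise test in the first comparison (0 adjusted over the list alone), although the list did (camera adjusted p = 0.000261, adjusted p = 0.614 with an estimated correlation), and all 10 were higher past the threshold without luminal-derived AD replicate 3 (camera adjusted p = 3.36e-18).

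In total 729 genes were higher and 326 lower in basal-derived than in luminal-derived AD cells (limma, adjusted p under 0.05). The balance of directions depended on the scaling. The share of higher genes was 69.1% as deposited, 59.0% with a trimmed mean, 55.2% with median-of-ratios, 44.9% with upper-quartile scaling (467 higher, 574 lower) and 48.3% with limma-voom on recovered reads (712 higher, 761 lower), and upper-quartile scaling moved the median log2 change of all genes from 0.098 to -0.057. Limma-voom used the median-of-ratios factors too, and the 2 moved that median by nearly the same amount (-0.0939 and -0.0916). Fewer genes passed without basal-derived AD replicate 1 (249 higher, 108 lower), replicate 2 (292, 115) or replicate 3 (242, 100), without luminal-derived AD replicate 2 (492, 184), and, for the shallow library with seminal vesicle transcripts, without luminal-derived AD replicate 3 (506, 242). The lists that camera did not call had camera adjusted p of: luminal epithelium 0.962, proximal luminal progenitor 0.925, androgen response 0.4, MHC class I 0.4, MHC class II 0.788, neuroendocrine 0.925, PI3K and FOXO feedback 0.279, p53 and senescence 0.925, myeloid cells 0.925, lymphocytes 0.925, smooth muscle 0.171, endothelium 0.962, glia 0.579 and mitochondrially encoded genes 0.788. Fry called 1 of these, androgen response, in the lower direction (fry adjusted p = 0.0107), against a median log2 change of 0.0187. It did not call the NF-kB (0.517), interferon (0.113), mesenchymal (0.0978), cholesterol (0.251), unfolded protein response (0.321), immediate-early (0.0976) or seminal vesicle list (0.161). Without luminal-derived AD replicate 3 camera called smooth muscle higher (camera adjusted p = 0.0294, median log2 change 0.642 against 0.392 with it).

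The second comparison asked how basal-derived luminal tumour cells of the ventral lobe differed from those of the anterior and dorsal lobes. The 12 genes that fell most by the naming rule had ventral means of at most 2.55 CPM, the level of Onecut2. Hnf4a, a nuclear receptor of liver and gut epithelium (chromosome 2, 163506808 to 163572910), was 82.95-fold lower, at 0.30 ± 0 against 30.5 ± 11.4 CPM (SD, n = 2 and 3, log2 fold change -6.37, SE 0.32, limma adjusted p = 5.57e-06). That ventral level lay under the floor of 3 reads (0.412 and 0.411 CPM), so the SD of 0 does not show the spread and the fold change is uncertain. The transcription factor Onecut2 was 86.1-fold lower (2.55 ± 1.27 against 216 ± 64.0 CPM). The oxidase gene Duox2 and its maturation factor Duoxa2 were 76.1-fold and 75.5-fold lower, Ctse, an aspartic protease gene, was 62.5-fold lower, and the antimicrobial lectin gene Reg3b was 96.1-fold lower. Without basal-derived VP replicate 2 the limma adjusted p of Duox2 was 0.0538. Reg1 had 1 read over the ventral and 921 over the AD libraries, a ratio of 601 with a 95% counting interval of 108 to 23700. Klk1 and Cyp21a1 had 3 reads each over the ventral libraries, with ratios of 91.7 (31.2 to 447) and 39.3 (13.2 to 193). Hmgcs2, a ketone body synthesis gene, Myo7b, a brush border myosin gene, and the fibroblast marker Pi16 were 29.2-fold, 21.9-fold and 23.8-fold lower. Reads of Reg1 and Reg3b can be shared with relatives in the same cluster. Limma-voom on recovered reads did not call Hnf4a, Reg1, Reg3b, Duox2, Duoxa2, Klk1 or Ctse, as given below.

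On the deposited scale fewer genes were higher than lower in ventral cells, a balance that upper-quartile scaling narrowed (742 higher, 1044 lower) and limma-voom did not show (698 higher, 671 lower). Fap, a cell surface protease, was 14.7-fold higher (53.3 ± 30.2 against 3.67 ± 2.25 CPM, limma adjusted p = 0.00948). The secretoglobin genes Scgb2b7 and Scgb2b27, whose reads can be shared within their family, were 8.88-fold and 5.76-fold higher. Scgb2b27 had limma adjusted p of 0.0654 to 0.0896 without basal-derived AD replicate 2 or 3 or either ventral library. The netrin receptor gene Unc5c was 6.85-fold and the lipoxygenase gene Aloxe3 6.12-fold higher, and Mcm10, a DNA replication gene, was 4.92-fold higher (29.1 ± 3.89 against 5.93 ± 1.31 CPM). Ido2, Chrna9, Trim72, Dnah12, Ampd1 and Spred3 were 5.43-fold to 7.40-fold higher at ventral means of 5.70 to 16.6 CPM, and leaving out basal-derived VP replicate 1 ended each of the 6 calls (limma adjusted p of 0.0524 to 0.16). Basal-derived AD replicate 3 did so for Chrna9, Trim72, Dnah12 and Spred3, basal-derived AD replicate 2 for Chrna9, Trim72 and Spred3, and basal-derived VP replicate 2 for Chrna9. Among lineage genes, Krt5 was 2.23-fold lower (limma adjusted p = 0.0023), Krt14 was 1.97-fold lower (limma adjusted p = 0.00286) and Krt15 was 4.75-fold lower (limma adjusted p = 0.00812, and 0.0513 with no filter on low values) in ventral cells. Ar was 1.41-fold lower (limma adjusted p = 0.045), a call that ended with median-of-ratios, upper-quartile and trimmed-mean scaling and limma-voom, and without any 1 of the basal-derived libraries or luminal-derived AD replicate 2 (limma adjusted p of 0.0548 to 0.201). Pten, Trp63, Krt8, Krt18, Epcam and Nkx3-1 had limma adjusted p of 0.225, 0.106, 0.824, 0.989, 0.566 and 0.272. Trp63 passed without luminal-derived AD replicate 1 or 2 (limma adjusted p of 0.0396 and 0.0464) or with only the 2 groups compared (0.02), and Nkx3-1 without basal-derived VP replicate 1 (0.0345).

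**Figure D3:**
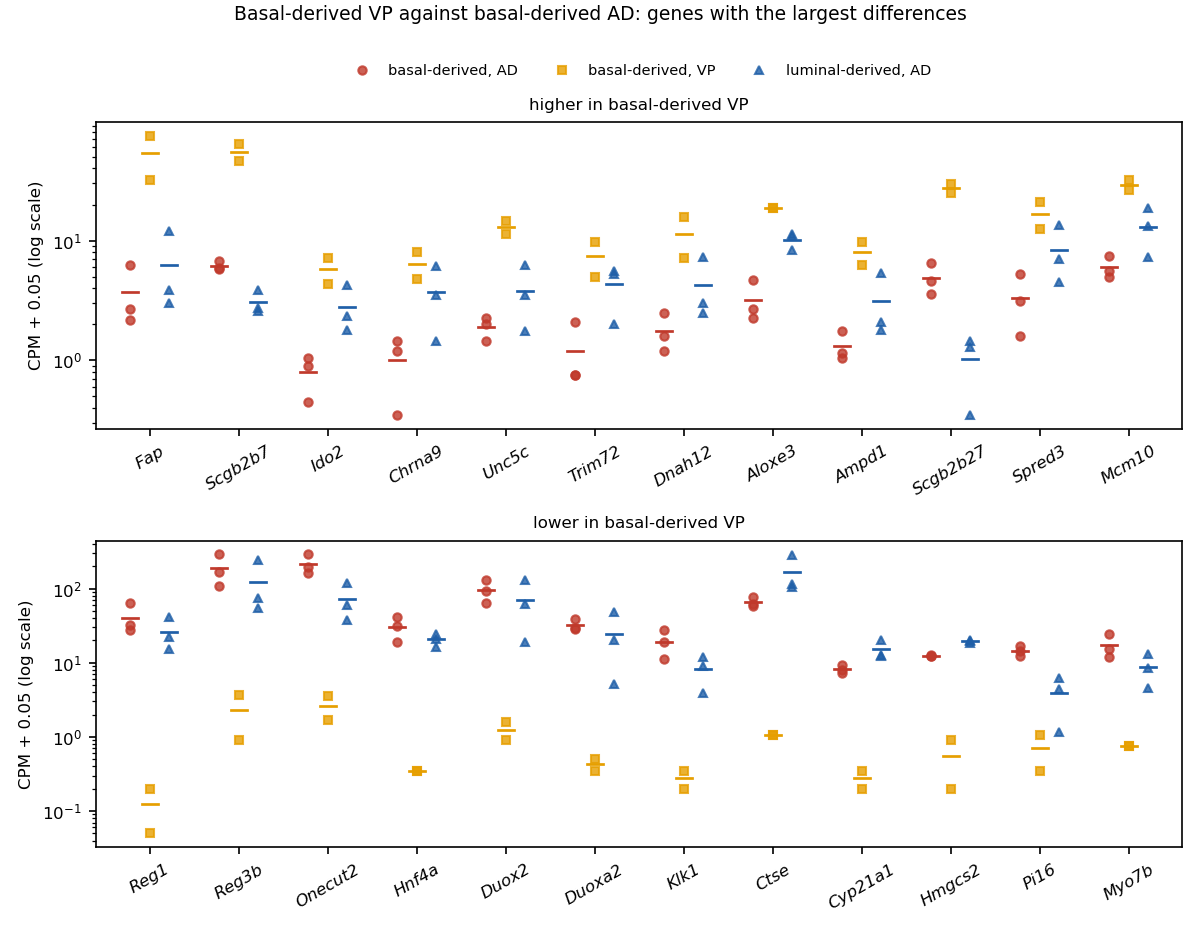
The 12 higher and the 12 lower genes that the naming rule picked in basal-derived VP against basal-derived AD cells, per library. The rule passes over genes with a mean under 1 log2 CPM, whatever their change. Values are CPM plus 0.05 on a log axis, with short lines at group means. Luminal-derived AD libraries are drawn for reference, and Hnf4a lies at 0.30 CPM in both ventral libraries.

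Of 36 interferon response genes 11 rose and none fell in ventral cells, and 26 rose adjusted over the list alone (camera adjusted p = 1.07e-15, adjusted p = 0.283 with an estimated correlation). The count of 11 was 6, 3 and 2 without basal-derived AD replicate 1, 2 or 3, 2 and 18 without ventral replicate 1 or 2, and 17 without luminal-derived AD replicate 1. Rsad2, an antiviral enzyme gene, was 2.7-fold higher (1244 ± 188 against 458 ± 15.4 CPM, limma adjusted p = 0.00273), Oas1b was 3.28-fold, Stat2 2.08-fold and Irf9 1.54-fold higher. Oas1b and Stat2 lost their calls without basal-derived AD replicate 3 or ventral replicate 1, and Stat2 also without basal-derived AD replicate 2 (limma adjusted p of 0.0521 to 0.0896). The list summed to 8487 against 4427 CPM. Of 34 innate effectors 11 fell (13 lower and 2 higher adjusted over the list alone, and 6 to 7 lower over all genes without basal-derived AD replicate 1 or 2 or ventral replicate 2), including Reg3g (11.1-fold), Chil1 (8.18-fold), Cfh (6.98-fold) and C1s1 (5.35-fold). The camera adjusted p was 0.000455 (adjusted p = 0.283 with an estimated correlation). Over all genes 1 innate effector rose without luminal-derived AD replicate 1 or 2 or ventral replicate 2, and 2 rose without luminal-derived AD replicate 3. Neutrophil markers fell beside them, 4 of 7 (also 4 adjusted over the list alone), with S100a9 13.3-fold and Csf3r 8.75-fold lower (camera adjusted p = 0.000759, adjusted p = 0.283 with an estimated correlation). Without basal-derived AD replicate 2 or ventral replicate 2 only 2 of the 7 fell, and S100a9 lost its call without these or basal-derived AD replicate 1 or with no filter on low values (limma adjusted p of 0.0515 to 0.0953).

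Of 14 neuroendocrine genes 11 fell in the ventral cells (12 adjusted over the list alone, camera adjusted p = 2.34e-10, adjusted p = 0.1 with an estimated correlation), among them Ascl1, the proneural transcription factor (13.0-fold, 0.375 ± 0.106 against 5.47 ± 1.1 CPM), Chga (14.75-fold) and Ncam1 (8.47-fold). Pcsk1 had 2 reads against 161, a ratio of 52.5 with a counting interval of 14.3 to 437. Over all genes 7 fell without basal-derived AD replicate 2 or 3 or ventral replicate 2. Glial markers fell with them, 5 of 7 (also 5 adjusted over the list alone, camera adjusted p = 5.11e-05, adjusted p = 0.1 with an estimated correlation), and Ncam1 stands in both lists. S100b had no read in the ventral libraries and was 4.78-fold lower at a floor of 3 counts over the group. Its counting interval began at 3.57-fold. Its call ended without any 1 basal-derived AD library or ventral replicate 2 (limma adjusted p of 0.0529 to 0.119) and with pseudocount 20 (0.102). Of the glial markers 3 fell without basal-derived AD replicate 2 or ventral replicate 2, and 2 without basal-derived AD replicate 3.

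**Figure D4:**
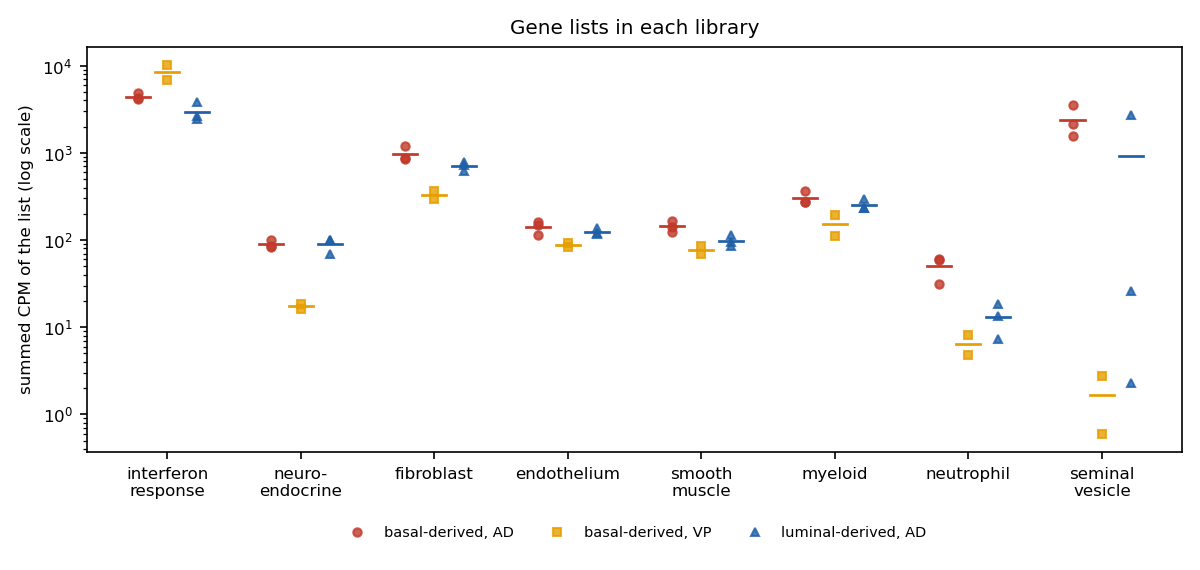
Summed CPM of 8 gene lists in each library on a log axis, with 1 symbol per library and short lines at group means. Interferon genes sum to 10060 and 6913 CPM in the ventral libraries, and seminal vesicle genes to 2700 CPM in luminal-derived AD replicate 3.

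Camera called the fibroblast, mesenchymal, myeloid, endothelial and smooth muscle lists lower in the ventral libraries, and not the lymphocyte list (camera adjusted p = 0.132). Of 18 fibroblast markers 16 fell and 1, Col6a3, rose (the same counts adjusted over the list alone), with Col1a2 8.70-fold and Thy1 18.0-fold lower (camera adjusted p = 8.26e-15, adjusted p = 0.157 with an estimated correlation). Without ventral replicate 1 there were 16 that fell and 2 that rose. Of 23 mesenchymal genes 10 fell (16 adjusted over the list alone), including Mmp2 (10.3-fold), Col5a1 (7.87-fold) and Sparc (6.45-fold), with a camera adjusted p of 4.33e-11 (adjusted p = 0.268 with an estimated correlation). Of 24 myeloid markers 11 fell (15 adjusted over the list alone, camera adjusted p = 5.81e-09), of 13 endothelial markers 7 fell (8 adjusted over the list alone, camera adjusted p = 5.17e-05), and of 10 smooth muscle markers 5 fell (also 5 adjusted over the list alone, camera adjusted p = 4.97e-05). Each of these 3 had an adjusted p = 0.283 with an estimated correlation. The myeloid count was 5, 7 and 6 without basal-derived AD replicate 1, 2 or 3 and 3 without ventral replicate 2, the endothelial count 4 without basal-derived AD replicate 1 or 2, and the smooth muscle count 3 without basal-derived AD replicate 1 or 3 or ventral replicate 2. Seminal vesicle genes had a camera adjusted p of 2.53e-07 (adjusted p = 0.283 with an estimated correlation). Of these 10 genes 1 fell past the gene-wise threshold and 10 adjusted over the list alone. That gene, Spinkl, had no read in ventral libraries and was 65.0-fold lower at the floor of 3 counts over the group. Its counting interval began at 52.5-fold. Without any 1 basal-derived AD library, either ventral library or luminal-derived AD replicate 1 its limma adjusted p was 0.075 to 0.251 and none of the 10 fell, while 3 fell without luminal-derived AD replicate 2 and all 10 without luminal-derived AD replicate 3. Its call also ended with pseudocount 5 (0.066), pseudocount 20 (0.0798) and no filter on low values (0.159).

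Of 20 basal genes 6 fell (13 fell and 1 rose adjusted over the list alone, camera adjusted p = 4.97e-05), of 17 proximal luminal progenitor genes 5 fell (9 adjusted over the list alone, camera adjusted p = 0.000956) and of 20 Hox and patterning genes 7 fell (9 adjusted over the list alone, camera adjusted p = 0.00051). Each had an adjusted p = 0.283 with an estimated correlation. Of the basal genes 10 fell without ventral replicate 1, and 1 rose without luminal-derived AD replicate 3. Of the progenitor genes 3 fell without basal-derived AD replicate 2, 2 without basal-derived AD replicate 3, and 2 fell and 1 rose without ventral replicate 2. Of the Hox and patterning genes 3 fell without basal-derived AD replicate 1 or 3, 4 without basal-derived AD replicate 2 or ventral replicate 2, and 2 rose without ventral replicate 1. Krt4 was 2.96-fold lower, Clu 2.00-fold lower (2866 ± 348 against 5707 ± 298 CPM, limma adjusted p of 0.0502 and 0.0575 without basal-derived AD replicate 3 or ventral replicate 2) and Hoxb9 3.27-fold lower. Shh had no read in the ventral libraries and was 4.78-fold lower at the floor of 3 counts over the group. Its counting interval began at 3.57-fold, and its limma adjusted p was 0.0595 with pseudocount 20. Of 26 immediate-early genes 6 fell, with Nr4a1 1.78-fold lower (6 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.542 with an estimated correlation), and the camera adjusted p was 0.972 without basal-derived VP replicate 1. The count of 6 was 2, 3 and 2 without basal-derived AD replicate 1, 2 or 3. Without ventral replicate 1, 1 fell and 1 rose and Nr4a1 had a limma adjusted p of 0.0544, and 1 rose without luminal-derived AD replicate 2. Of 25 cholesterol synthesis genes Mvd and Hmgcs1 fell (also 2 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.71 with an estimated correlation), and the camera adjusted p was 0.128 without basal-derived AD replicate 3 and 0.356 without basal-derived VP replicate 1. Neither gene fell without any 1 basal-derived AD library or ventral replicate 2, and Hmgcs1 did not without ventral replicate 1 or luminal-derived AD replicate 3 (limma adjusted p of 0.0529 to 0.186). Upper-quartile scaling ended the call of Mvd (0.057), pseudocount 0.1 that of Hmgcs1 (0.0519), and leaving out ribosomal RNA related features both (0.0515 and 0.0512). The 13 mitochondrially encoded genes were higher as a list, with none past the gene-wise threshold or adjusted over the list alone (camera adjusted p = 0.0319, adjusted p = 0.542 with an estimated correlation, and 0.192 and 0.0956 by camera without basal-derived AD replicate 3 or VP replicate 2).

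In total 384 genes were higher and 1203 lower in ventral than in AD basal-derived cells (limma, adjusted p under 0.05), and 513 and 1380 without luminal-derived AD replicate 3. The share of higher genes was 24.2% as deposited, 41.5% with upper-quartile scaling (742 higher, 1044 lower, the median log2 change of all genes moving from -0.041 to 0.059) and 51.0% with limma-voom on recovered reads (698 higher, 671 lower), under which Reg1, Reg3b, Hnf4a, Duox2, Duoxa2, Klk1, Ctse, S100a9, S100b, Chga, Pcsk1, Hoxb9, Shh, Spinkl and Mvd had adjusted p of 0.0621 to 0.431 by limma-voom. Counts fell without basal-derived AD replicate 1 (188 higher, 699 lower), replicate 2 (138, 691) or replicate 3 (96, 625), and without basal-derived VP replicate 1 (218 higher). The lists that camera did not call were luminal epithelium (camera adjusted p = 0.359), secretory proteins (0.232), androgen response (0.166), NF-kB targets (0.626), MHC class I (0.111), MHC class II (0.295), cell cycle (0.249), squamous differentiation (0.249), PI3K and FOXO feedback (0.179), p53 and senescence (0.626), hypoxia and glycolysis (0.587), unfolded protein response (0.232) and lymphocytes (0.132). Fry called 2 of these in the lower direction, androgen response (median log2 change -0.0781, fry adjusted p = 0.00633) and squamous differentiation (median -0.461, fry adjusted p = 0.0479). It did not call the interferon (0.0586), seminal vesicle (0.0504), immediate-early (0.114), cholesterol (0.329) or mitochondrial list (0.256).

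The ventral basal-derived cells were last set against the luminal-derived AD cells, a comparison that differs in both origin and lobe. Hdac9 was 54.5-fold higher (167 ± 43.8 against 3.05 ± 0.95 CPM), Saa1 was 35.5-fold higher, and Pbsn and Tgm4 were 137-fold and 82.0-fold lower. Of 36 interferon genes 30 rose (33 adjusted over the list alone), with Ifit1 4.64-fold and Irf1 2.32-fold higher (camera adjusted p = 3.7e-23, adjusted p = 0.336 with an estimated correlation). The count of 30 was 26 without luminal-derived AD replicate 2 and 32 without replicate 1. The list summed to 10060 and 6913 CPM in ventral replicates 1 and 2, against 3820, 2618 and 2417 CPM in the luminal-derived AD libraries. Camera called 18 of 30 lists, 6 higher and 12 lower. Among the lower ones were neuroendocrine genes (11 of 14 lower, 7 without basal-derived VP replicate 2, also 11 adjusted over the list alone, camera adjusted p = 7.56e-11, adjusted p = 0.137 with an estimated correlation) and fibroblast markers (13 of 18 lower and 1 higher, 16 and 1 adjusted over the list alone, camera adjusted p = 2.55e-11, adjusted p = 0.26 with an estimated correlation). Of 2145 genes past the threshold 876 were higher and 1269 lower (limma). Without luminal-derived AD replicate 3 the counts were 655 and 1141, and without basal-derived VP replicate 2 they were 565 and 840. Without luminal-derived AD replicate 1 the balance turned, with 1263 higher and 1151 lower, and limma-voom (507 and 632) and a fit of only the 2 groups (370 and 704) called fewer genes. With the first comparison, which uses the same luminal-derived libraries, 317 higher and 176 lower calls were shared and 36 went opposite ways. Independent lists would share 33.9 and 22, and 100 simulations of unchanged groups against shared luminal-derived libraries gave at most 1 and 1. No gene differed in those simulations, so few calls could arise. They do not measure how many of the shared calls come from the shared libraries. The covariance of the log2 changes was 0.371 against 0.0995 simulated, a difference of 0.272, and the correlation 0.468 against 0.449. The 3 luminal-derived libraries cannot be split into parts of at least 2, so part of the excess may come from the shared libraries.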

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

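Pseudocount 20, trimmed-mean scaling, leaving out ribosomal RNA related features and leaving out genes that follow the seminal vesicle score were chosen after seeing the data. The last left out 90 genes, without a new fit, and gave 725 higher and 326 lower in the first comparison. Of the 90 genes 4 had been called higher and 0 lower. Since that score is high in luminal-derived AD replicate 3 and low in replicates 1 and 2, few such genes could be called. These counts therefore do not test seminal vesicle carry-over. Of 5966 values of named genes under other settings 5400 kept their side of the threshold, 501 lost the call, 60 gained it and 5 reversed with a call in either fit. The 5400 include any changes of direction where neither fit called the gene. Of 1188 values of called lists 1058 kept the call and its direction, 128 lost the call and 2 reversed, and of 208 counts 165 stayed within 1.5 times. The calls lost most often were Defb50 (17 settings), Postn (15) and Peg10 (14) in the first comparison, Spinkl (12) and Ar (11) in the second and Sbp (15) in the third. Tests of counts with edgeR and DESeq2 that had been planned were not run, because the deposited values are not counts. Depth limits luminal-derived AD replicate 3 most, where a floor of 3 reads is 1.03 CPM.

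Upper-quartile scaling gave 467 higher and 574 lower genes in the first comparison and 742 higher in the second. Limma-voom on recovered reads gave 761 lower in the first, 698 higher and 671 lower in the second, and 507 and 632 in the third. Testing against a 1.5-fold change, a stricter question, left 100 and 41, 26 and 365, and 177 and 433 genes in the 3 comparisons. With only the 2 groups compared, and so fewer samples, there were 628 higher in the second and 370 higher and 704 lower in the comparison of VP with luminal-derived AD cells. The mean of both basal-derived groups against luminal-derived cells gave 778 lower genes in the first comparison, and reversed the medians of the mesenchymal list to -0.323 and of the fibroblast list to -0.332 and the log2 changes of Mmp2 (-0.323), Sparc (-0.1941), Fbln1 (-0.2106), Col1a2 (-0.2727) and Pmp22 (-0.8255), since the ventral libraries then enter. For the other settings the cause was not tested. Camera with an estimated correlation called 0, 0 and 0 lists, and fry called 10 in the first comparison. Shared calls of the first and the third comparison at an adjusted p under 0.01 were 117 higher and 56 lower.

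The replicate block gave 1263 higher and 567 lower genes in the first comparison and 615 higher in the second. Under it Spink5, Peg10 and Defb50 (first comparison) and Reg3b and Duox2 (second) were not called (limma adjusted p of 0.0592 to 0.137), nor were the secretory list (first, camera adjusted p = 0.0535) and the cholesterol and mitochondrial lists (second, 0.108 and 0.0758), and Trp63 was called in the second (0.0251). The MHC class I and II lists were also called in the second (camera adjusted p of 0.00839 and 0.0262), with 2 genes higher and 2 lower. In the first comparison 20 interferon and 14 cell cycle genes rose under the block. Libraries with the same number had correlations of deviations of 0.0581 to 0.385 over 7 pairs, against -0.385 to 0.276 over 14 other pairs. The 2 ventral libraries deviate from their mean by equal amounts in opposite directions. Each ventral correlation therefore appears with both signs, and these pairs are not separate evidence. Not every pair passed 0.1 and no label ties the numbers, so they were not taken as pairs. Between the 2 AD groups every library correlated best with its own number, a hint from the data only. Basal-derived VP replicate 2 did not, with 0.276 to basal-derived AD replicate 3 against 0.205 to replicate 2, but these values only mirror those of VP replicate 1.

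Leaving out 1 library at a time gave 242 to 970 higher and 100 to 467 lower genes in the first comparison, 96 to 513 and 625 to 1380 in the second, and 565 to 1263 and 840 to 1262 in the third. Where a group was left with 1 ventral library, it was assumed to vary like the other groups.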

Other observations

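The tests of leftover basal cells, of low depth as the whole cause and of a smaller share of non-epithelial cells were chosen after the result was seen. Some lists that camera did not call held genes that moved, among them the squamous list of the second comparison, which fry called lower (fry adjusted p = 0.0479). In basal-derived against luminal-derived AD cells, the proximal progenitor genes Krt4 and Lypd3 were 2.42-fold and 6.04-fold higher and Wfdc2 was 1.66-fold lower (limma adjusted p of 0.000506, 0.000206 and 0.00932). Wfdc2 had a limma adjusted p of 0.0535 without basal-derived AD replicate 1. The PI3K and FOXO feedback genes Pik3r1, Cdkn1b and Ccng2 were 1.85-fold, 1.68-fold and 1.43-fold higher (limma adjusted p of 0.00501, 0.00665 and 0.0231). Ccng2 lost its call without any 1 basal-derived AD library or luminal-derived AD replicate 2 and with upper-quartile scaling (limma adjusted p of 0.0739 to 0.115). In ventral against AD basal-derived cells, the cornified envelope gene Ivl was 10.2-fold lower and Ly6d 2.52-fold lower, while Krt80 was 1.78-fold higher (limma adjusted p of 0.0505 and 0.0636 without basal-derived AD replicate 3 or VP replicate 2). The matrix protease gene Mmp7 was 15.7-fold lower (14.2 against 207 CPM, limma adjusted p = 0.000642).

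Hdac9 separated the 3 groups, with 36.7, 47.05 and 50.85 CPM in basal-derived AD, 135.9 and 197.8 CPM in basal-derived VP, and 4.15, 2.55 and 2.45 CPM in luminal-derived AD libraries. It was 3.69-fold higher in ventral than in AD basal-derived cells (limma adjusted p = 0.00166), a value read after the rule had named it for the first comparison. Sbp, a secreted protein gene, stood at 2048 and 2661 CPM in ventral and at 542.8 to 824.3 CPM in basal-derived AD libraries. Its luminal-derived AD levels of 2.05, 3.85 and 111.9 CPM spread widely, and it passed the threshold neither between the AD groups nor between the basal-derived groups (limma adjusted p of 0.102 and 0.621). Without luminal-derived AD replicate 3 it passed both (2.05e-05 and 0.00953), as it did between the AD groups with limma-voom (0.0205) or the mean of both basal-derived groups (0.0439), and between the basal-derived groups with only the 2 groups compared (0.00167). Ventral against luminal-derived AD cells gave a limma adjusted p of 0.0497, 0.0807 to 0.175 without any 1 library except luminal-derived AD replicate 3, 0.0521 to 0.0522 with the other scalings or without ribosomal RNA related features, 0.0746 with no filter on low values and 0.153 with only the 2 groups compared.

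Only 1 of the 10 splits of the 6 AD libraries, the real one, gave as many as 1055 called genes (highest other 0), and 10 splits are too few for a share under 0.05. RNA carried over from seminal vesicle is argued against as the cause of most higher calls. Without luminal-derived AD replicate 3, 506 genes were called higher. In that library they lay at a median of -1.21% of the way from the other luminal-derived libraries to the basal-derived level. The seminal vesicle list lay at 102%. Of the 506 genes 63 (12.5%) lay past the midpoint, and carry-over stays open for these. The 242 genes called lower had a median of 22.8% in that library, with 57 (23.6%) past the midpoint. Low depth of that library is argued against as the whole cause, since 636 of 1055 called genes were called in the same direction without it, but it stays open for the other genes: the share called without it was 60.3%, within the 32% to 77.3% seen when other AD libraries were left out. Cell of origin, which the design names, also stays open, and model and origin are the same split here.

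Leftover basal cells in the sort may raise the basal keratins. Of the basal list 1 gene, Lamc2, fell past the threshold, and none without any 1 basal-derived AD library or luminal-derived AD replicate 1 or 2, which is too few to exclude this. The 17 other basal genes changed by 0.80 on average (SE 0.23, log2), as mixed-in cells would also give. The ratio of Krt15 to Krt5 was 7.88 ± 0.152 in basal-derived AD, 4 ± 2.11 in basal-derived VP and 3.94 ± 1.19 in luminal-derived AD libraries. Basal genes kept by luminal cells of basal origin remain a hypothesis that these data cannot set apart from leftover cells.

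Genes lower in ventral cells stood, in luminal-derived AD replicates 1 and 2, at a median of 81.1% of the way from the ventral to the basal-derived AD level (lower quartile 54.1%). The seminal vesicle list stood at 4.54%. These values argue against RNA carried over from seminal vesicle as the cause of most of these calls. A smaller share of non-epithelial cells could lower marker genes together: fibroblast markers fell by 2.31 (SE 0.203), endothelial by 1.51 (SE 0.393), smooth muscle by 1.39 (SE 0.248) and myeloid by 1.46 (SE 0.404) on the log2 scale. Past the threshold 16 of the 18 fibroblast markers fell and 1, Col6a3, rose. Of the 3 other classes 1 differed from fibroblasts by over 3 standard errors (smooth muscle, 5.63), so a smaller share of non-epithelial cells stays open. Stromal carry-over as the source of the 12 named lower genes, Hnf4a and the fibroblast marker Pi16 among them, could not be decided over the 6 AD libraries. Pearson r was 0.466 (exact permutation p = 0.368) and Spearman rho 0.371 (exact permutation p = 0.497). The AD groups do not overlap in the fibroblast score. Without the 2 libraries farthest from its median, basal-derived AD replicate 1 and luminal-derived AD replicate 2, r was 0.927. That r rests on few libraries and mostly on the difference between the groups. Luminal-derived AD replicate 2 had the lowest fibroblast score (7.93) beside a score of 9.44 for the 12 genes. Lobe of origin stays open and untested.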
